A study of Citrus x clementina and Citrus japonica with 6 samples.

How the data were processed

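RNA-seq of fruit from Clementine mandarin and kumquat was analysed, with 3 libraries per species. Per the labels, total RNA was taken with TRIzol and treated with DNase I, and libraries were made and sequenced on an Illumina instrument by a sequencing company. Per the series' design text, fruit of different stages was pooled for each library. The submitters' processing notes name HISAT, StringTie and DESeq2, with no versions and no roles. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Gene model identifiers are those of the table.

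The deposited file is 1 table of FPKM per gene model, which the authors made from their reads and wrote with 2 decimals, per the file headers and the values. Each of the 30139 rows has a transcript identifier equal to its gene identifier, so a row is called a gene model here. The same table gives GO terms, KEGG orthology names (22592 models) and the best protein match. For 27970 models this match is a hypothetical protein. Names are those of the closest family, some of them animal names, and are given as annotations. A model can carry several KEGG names. There are 21944 distinct matches, and 4706 of them are shared by 2 or more models, 12901 models in all.

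FPKM are not counts. The design written before the data were examined gave separate tests for counts and for normalized values, and the branch for normalized values was used. The total depth is unknown. In values from 0.2 to 1 FPKM, the most frequent ratio between libraries gave relative depths of 0.959, 1.00 and 1.00 for clementine replicates 1 to 3 and 0.871, 0.920 and 0.920 for kumquat replicates 1 to 3. No intervals from counting error can be given. An FPKM of 0 can be a failed estimate in fragment assignment, so a model at 0 in all libraries of a group is said to be listed at 0, with no fold.

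Models with at least 1 FPKM in at least 3 libraries were tested, 22050 in all. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance, the contrast kumquat minus clementine and no covariate. A model was called at a Benjamini-Hochberg adjusted p under 0.05, and counted again at a change of at least 2-fold. Tests are two-sided. The median SD within a species was 0.168 on the log2 scale.

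The 22 gene lists were text patterns fixed before the data were examined and matched to the KEGG names and the protein match. They covered carotenoid biosynthesis, carotenoid cleavage and abscisic acid, flavonoids, phenylpropanoids and lignin, terpenes, sugars, organic acids, cell wall loosening, cellulose and secondary wall, cuticle and wax, photosynthesis, cell cycle, auxin, gibberellin, ethylene, ascorbate, MADS-box factors, disease resistance, heat shock, seed markers, ribosomal proteins and transposable elements. The lists of seed markers, photosynthesis, terpenes, cuticle and cellulose were also meant to stand for seeds, green tissue, oil glands, epidermis and vascular tissue. Lists with at least 5 tested members, 21 in all, were tested with limma's camera, which compares a list with all other models. It used a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and was run again with the correlation estimated from the data. The second run of camera takes its degrees of freedom from the few libraries instead of the many models. It therefore has far less power, and a higher p there need not come from correlation between genes. After the data were seen, the same test was added for KEGG and GO groups with at least 10 tested models, adjusted over 496 and 301 groups.

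Named models followed a rule fixed before the data were examined. It took the 5 largest rises and the 5 largest falls among called models with an informative name, no overlap between the species' libraries and a mean of at least 10 FPKM in the higher species. For each list it took the most abundant called member at least 2-fold higher and the most abundant at least 2-fold lower. Where a list had neither, its most abundant member would have been named. The rule gave 49 models.

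The test was checked on simulated data made from the real means and spreads, with 200 of 21580 models changed. It recovered 38% of 50 models changed by 0.5 on the log2 scale, 82% at 1, 96% at 2 and 100% at 3. Of 172 calls, 14 were of unchanged models, or 8.14%. The changed models were drawn only from those with a mean level of about 5 FPKM or more. Their share was also far smaller than the share called in the real data. These rates therefore need not hold for models at lower levels or for the real comparison. Alternatives tried were another pseudocount (0.1), no filter, a filter of 5 FPKM, scaling of each library to its median log ratio, the replicate number as a term, each library left out in turn, an estimated correlation and list patterns on the KEGG names alone. Chosen after seeing the data were the sum of models with the same protein match, an ethylene pattern at the start of a word and a count of all models named as ribosomal proteins.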

Results

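The series measured messenger RNA in fruit of kumquat (Fortunella japonica), a small citrus relative, and of Clementine mandarin (Citrus x clementina). It holds 6 RNA-seq libraries, 3 per species. Each library pooled fruit of 5 stages. Stages 1 to 3 were at 15, 30 and 45 days after flowering in both species. Stages 4 and 5 were at 100 and 180 days in clementine and at 80 and 120 days in kumquat, so species and fruit age differ together in every comparison. These ages stand in both the design text and the sample labels, but the stage label of the kumquat libraries calls the fruit Clementine mandarin while their cultivar label says kumquat. The design text says that materials came from 3 individual plants, without tying a library to a plant. The deposited table gave FPKM (fragments scaled to model length and library size) for 30139 clementine gene models. FPKM summed to between 691560 and 707892 per library. Between 25523 and 26285 models had a value above 0. Total fragment counts are unknown. Steps between low FPKM values gave each library's depth relative to clementine replicate 2, from 0.871 in kumquat replicate 1 to 1.00 in clementine replicate 3.

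The study's title names a comparison of fruit traits between the 2 species, and the libraries address which gene models differ in level between the fruits. Fruit of the 2 species differed across a large part of the transcriptome, with about as many models higher as lower in kumquat. Of 22050 models tested, 12582 were called with limma at a Benjamini-Hochberg adjusted p under 0.05. These were 6602 models higher and 5980 lower in kumquat. With a change of at least 2-fold in addition, 2741 were higher and 2672 lower. The most abundant kumquat model, Ciclev10009848m, has a match of unknown function and took 2.45 to 2.71% of the FPKM sum of each kumquat library. Its level was 1333 ± 102 FPKM in clementine and 18130 ± 1128 in kumquat (SD, n = 3 each), and it was chosen after its values were seen. Pearson's r of log2(FPKM + 1) across models, which are not independent replicates, was 0.974 to 0.981 within a species and 0.879 to 0.884 between species. The first principal component held 82.9% of the variance and separated the species.

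**Figure D1:**
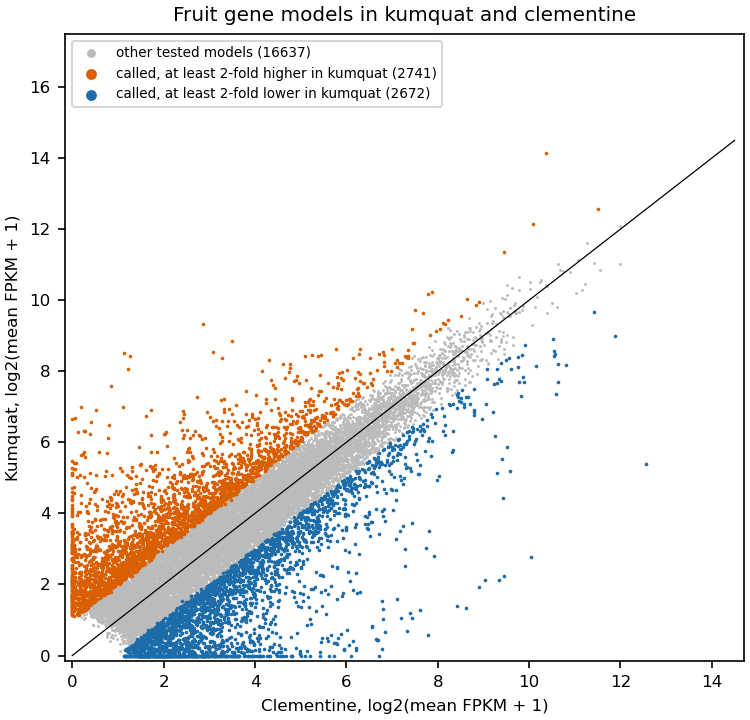
Each point is a tested gene model, with log2(mean FPKM + 1) of 3 clementine libraries on the x axis and of 3 kumquat libraries on the y axis. Orange marks the 2741 models called at least 2-fold higher in kumquat, blue the 2672 called at least 2-fold lower and grey the other 16637. The line marks equal levels.

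The naming rule gave the 5 annotated models with the largest rises and the 5 with the largest falls. Values are mean FPKM ± SD over 3 libraries per species, and fold changes are kumquat minus clementine on the log2(FPKM + 1) scale, which understates the change of low models. Ciclev10011377m, annotated as a laccase (an oxidase that acts on lignin precursors), stood at 1.18 ± 0.712 in clementine and 365 ± 45.9 in kumquat, a log2 change of 7.44. Ciclev10028504m, annotated both as shikimate O-hydroxycinnamoyltransferase, an enzyme of the lignin pathway, and as omega-hydroxypalmitate O-feruloyl transferase, an enzyme of suberin synthesis, stood at 1.41 ± 0.224 and 341 ± 11.4, a log2 change of 7.15. Ciclev10024109m, annotated as a SET and MYND domain protein, stood at 1.33 ± 0.820 and 265 ± 13.6. Ciclev10031236m, which carries the animal name steroid 17alpha-monooxygenase and so belongs with the cytochrome P450 enzymes, was at 0 to 0.34 in the clementine libraries and at 122 to 131 in kumquat. Ciclev10026665m, annotated as PAX-interacting protein 1, was listed at 0 in all 3 clementine libraries and at 92.6, 104.2 and 103.9 in kumquat. The sum of the 3 models that share its protein match was 93.6 in clementine and 102.3 in kumquat and was not called (adjusted p = 0.142, limma).

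Among the 5 largest falls, 3 models were annotated as caffeic acid 3-O-methyltransferase, which methylates lignin precursors. Ciclev10031949m stood at 1060 ± 65.2 in clementine and 5.89 ± 1.45 in kumquat, a log2 change of -7.29. Ciclev10031952m stood at 649.7 ± 25.6 and 3.36 ± 1.12, and Ciclev10031951m at 395 ± 23.8 and 1.54 ± 0.569. Each shares its match with other models, and the sums changed by -7.07, -6.27 and, for Ciclev10031951m, from 408.1 to 8.75 (log2 change -5.39 against -7.31). Ciclev10004868m, annotated as anthocyanidin 3-O-glucoside xylosyltransferase, which adds a sugar to anthocyanins, stood at 703 ± 11.9 and 3.76 ± 0.525, a log2 change of -7.21. The other was Ciclev10032873m, annotated as ADP-ribosylation factor 1, a small GTPase of vesicle transport. Its values were 327 to 365.5 in clementine and 1.63, 0 and 3.18 in kumquat. Summed with a second model of its match, the levels were 359.5 and 320.0 and were not called (adjusted p = 0.0898, limma). For these 10 models the SE of the log2 change lay between 0.0832 and 0.454, and the limma adjusted p between 1.9e-08 and 1.09e-05.

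Models of the phenylpropanoid and lignin list, one of 22 lists fixed before the data were examined, went both ways. Of 146 tested, 51 were higher in kumquat, 65 lower and 30 not called, and adjusted over the list alone 52 were higher and 66 lower. With models of the same protein match summed, 50 of 123 matches were higher and 50 lower. The list as a whole did not differ from other models (camera adjusted p = 0.383, median log2 change -0.21). Within it, all 6 models annotated as phenylalanine ammonia-lyase, the entry enzyme of the pathway, were lower, 4 of them at least 2-fold. Of 16 models of caffeoyl-CoA O-methyltransferase, 12 were lower and 1 higher (5 and 1 of 9 summed matches), and the most abundant, Ciclev10026344m, stood at 950.3 ± 17.1 in clementine and 207 ± 5.60 in kumquat. Of 17 laccases, 10 were lower and 3 higher, among the latter Ciclev10011377m. All 3 models of ferulate 5-hydroxylase were higher. Caffeic acid 3-O-methyltransferase, with 3 of the 5 largest falls, had 14 of 37 models higher and 16 lower (camera adjusted p = 0.661). Cinnamoyl-CoA reductase had 11 of 24 higher and 7 lower, cinnamyl-alcohol dehydrogenase 7 of 12 higher and 3 lower, and shikimate O-hydroxycinnamoyltransferase 6 of 13 higher and 3 lower (adjusted p = 0.749, 0.691 and 0.288). Families within lists were singled out after their counts were seen. Camera tests of KEGG families with at least 10 tested models, added after the data were seen, gave adjusted p = 0.00941 for caffeoyl-CoA O-methyltransferase (adjusted p = 0.869 with an estimated correlation) and 0.456 for laccase. Smaller families were not tested as groups.

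In the flavonoid and anthocyanin list, 43 of 112 tested models were higher, 49 lower and 20 not called, with the same 43 and 49 adjusted over the list alone (camera adjusted p = 0.714, median -0.04). Chalcone isomerase and chalcone synthase, which act early in flavonoid synthesis, had 4 of 5 and 4 of 7 models lower in kumquat, and 1 chalcone synthase model was higher. Summed by protein match, 2 of 3 chalcone isomerase matches were lower, and chalcone synthase had 4 of 7 lower and 1 higher. The most abundant model at least 2-fold higher was Ciclev10028904m, annotated as leucoanthocyanidin reductase, at 132 ± 5.14 in clementine and 299 ± 14.6 in kumquat. The most abundant at least 2-fold lower was Ciclev10004868m, given above.

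Carotenoid models went both ways. Of 60 tested models of carotenoid biosynthesis, 22 were higher, 21 lower and 17 not called, and adjusted over the list alone the split was 22 and 21 (camera adjusted p = 0.821, median -0.07). Ciclev10008369m, annotated as zeaxanthin epoxidase, which turns zeaxanthin into violaxanthin, was the most abundant model at least 2-fold lower, at 681.5 ± 36.9 in clementine and 44.9 ± 2.22 in kumquat (log2 change -3.90). Ciclev10028550m, which carries the names salicylate hydroxylase and zeaxanthin epoxidase, was higher at 7.54 ± 1.06 and 39.1 ± 5.89. Of 10 models of beta-ring hydroxylase, 6 were lower and 4 higher (camera adjusted p = 0.643), and of 7 models of prolycopene isomerase, 5 were higher and 2 lower.

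The list of carotenoid cleavage and abscisic acid had 14 of 43 tested models higher, 11 lower and 18 not called, and 14 and 11 adjusted over the list alone. Its camera adjusted p was 0.883. Its median of 0.06 and the direction of its test were positive, and its mean of -0.05 was negative. Ciclev10011655m, annotated as abscisic acid 8'-hydroxylase, the enzyme that starts the breakdown of this hormone, stood at 7.85 ± 2.56 in clementine and 87.6 ± 0.558 in kumquat (log2 change 3.37). Ciclev10012438m, annotated as momilactone-A synthase and as xanthoxin dehydrogenase, stood at 59.8 ± 6.04 and 2.39 ± 0.168. The list of terpene synthases and isoprenoid precursors was also meant to stand for oil glands. Of its 28 models 11 were higher, 5 lower and 12 not called, with 11 and 5 adjusted over the list alone (camera adjusted p = 0.694, median 0.18). Its named families include enzymes of isoprenoid precursors, such as geranylgeranyl diphosphate synthase with 7 models, so it cannot be read as a measure of oil glands. Ciclev10008936m, annotated as geranylgeranyl diphosphate synthase, stood at 1.78 ± 0.488 and 40.5 ± 6.77. Ciclev10014790m, annotated as alpha-farnesene synthase, stood at 65.9 ± 1.57 and 23.9 ± 1.52.

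In sugar metabolism and transport, 28 of 76 tested models were higher, 26 lower and 22 not called, and 30 and 27 adjusted over the list alone (camera adjusted p = 0.895, median 0.09). Once models with the same protein match were summed, 29 of 62 matches were higher and 17 lower (camera adjusted p = 0.612). Of 7 hexokinase models, 6 were higher and none lower. After median scaling 5 were higher, and of 6 summed protein matches 5 were higher and 1 lower. Of 15 sucrose synthase models, 9 were lower and 2 higher, but summed, 3 of 7 matches were higher and 2 lower (camera adjusted p = 0.375 for the 15 models). Ciclev10004341m, a sucrose synthase, stood at 16.5 ± 1.36 in clementine and 40.2 ± 5.66 in kumquat. Ciclev10007488m, another, stood at 194 ± 20.1 and 1.44 ± 0.892, a log2 change of -6.38. The sum of the 9 models of its match went from 852.5 to 567, a log2 change of -0.59.

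Organic acid metabolism and vacuolar acidification had 21 of 60 tested models higher, 16 lower and 23 not called, and 21 and 17 adjusted over the list alone (camera adjusted p = 0.714, median 0.06). Ciclev10007668m, annotated as NADP-dependent malic enzyme, which turns malate into pyruvate, stood at 162.5 ± 7.75 and 329 ± 23.4. Ciclev10001316m, annotated as isocitrate dehydrogenase, stood at 15.7 ± 4.35 and 4.04 ± 2.08 (log2 change -1.77), and the sum of its 4 models changed by -0.32. Of 5 models of phosphoenolpyruvate carboxykinase, 4 were higher and 1 lower, and their 2 summed matches were both higher. In the ascorbate list 10 of 33 models were higher, 11 lower and 12 not called, with 10 and 11 adjusted over the list alone (camera adjusted p = 0.750, median -0.02). Ciclev10014733m, annotated as ascorbate oxidase, stood at 1518 ± 27.0 in clementine and 359 ± 10.5 in kumquat. Ciclev10008868m, an ascorbate peroxidase, stood at 8.69 ± 1.33 and 19.9 ± 1.30.

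Both cell wall lists were lower in kumquat. In cell wall loosening and pectin breakdown, 71 of 167 tested models were lower, 33 higher and 63 not called, and 75 lower and 33 higher adjusted over the list alone. The camera adjusted p was 0.0276 (median -0.25), the adjusted p = 0.197 with an estimated correlation, and the adjusted p = 0.0963 with no filter on low values, where the median was -0.15. Pectinesterases, which remove methyl groups from pectin, had 23 of 43 models lower and 8 higher (camera adjusted p = 0.121). Polygalacturonases, which cut pectin, had 13 of 23 lower and 3 higher (adjusted p = 0.0341, and adjusted p = 0.869 with an estimated correlation). Of 9 models named TCH4, a xyloglucan-remodelling enzyme, 6 were higher and none lower. Ciclev10016129m, a xyloglucosyl transferase, stood at 780.5 ± 42.6 in clementine and 268 ± 22.5 in kumquat, and Ciclev10022313m, a pectinesterase, at 158 ± 4.51 and 339.7 ± 14.4.

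In cellulose and secondary wall, a list also meant to stand for vascular tissue, 22 of 38 tested models were lower, 5 higher and 11 not called, and 23 and 5 adjusted over the list alone. The camera adjusted p was 0.00632 (median -0.66), and the adjusted p = 0.297 with an estimated correlation. With no filter on low values the median was -0.38. Of these models 34 were annotated as cellulose synthase A, the name of the catalytic subunits, with 20 lower and 4 higher (adjusted p = 0.0388, and adjusted p = 0.869 with an estimated correlation). Most members thus carry a single family name, and the list cannot be read as a measure of vascular tissue. Ciclev10027605m, whose protein match is cellulose synthase-like B4, stood at 25.4 ± 4.56 in clementine and 9.72 ± 0.754 in kumquat. Ciclev10004394m, a cellulose synthase A, was higher at 52.1 ± 1.45 and 148 ± 4.87. For cuticle and wax, a list also meant to stand for the epidermis, 32 of 94 models were higher, 21 lower and 41 not called, with 32 and 21 adjusted over the list alone (camera adjusted p = 0.750, median 0.07). Its pattern caught many acyltransferases, 29 models named glycerol-3-phosphate O-acyltransferase 3/4 (9 higher, 7 lower) and 16 named 1-acyl-sn-glycerol-3-phosphate acyltransferase (7 higher, 1 lower). The list therefore cannot be read as a measure of epidermis. Of 11 fatty acyl-CoA reductases, which make wax alcohols, 3 were higher and 5 lower (camera adjusted p = 0.660). Among them, Ciclev10011477m stood at 143 ± 3.20 and 10.4 ± 1.26, and Ciclev10028415m at 19.6 ± 1.25 and 84.6 ± 2.41.

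Photosynthesis and chlorophyll models, which mark green tissue, were lower in kumquat. Of 64 tested, 34 were lower, 7 higher and 23 not called, and 34 and 7 adjusted over the list alone. The camera adjusted p was 0.000967 (median -0.43), and the adjusted p = 0.307 with an estimated correlation. Ciclev10002129m, a light-harvesting protein of photosystem I, stood at 303 ± 17.4 in clementine and 135 ± 7.05 in kumquat. Ciclev10009707m, a small chain of Rubisco, was listed at 0, 0 and 1.35 in clementine and stood at 23.1, 17.7 and 11.2 in kumquat. The sum with the second model of its match was 30.9 and 32.5 (adjusted p = 0.553, limma). The cell cycle and DNA replication list was even as a whole, with 20 of 77 higher, 20 lower and 37 not called, the same 20 and 20 adjusted over the list alone (camera adjusted p = 0.750, median -0.06), and 14 of 56 summed matches higher and 19 lower. Its 2 largest families leaned to higher. The 20 models named as the checkpoint protein MAD1 had 8 higher and 2 lower (camera adjusted p = 0.551). The 20 named cyclin-dependent kinase 12/13 had 9 higher and 5 lower (adjusted p = 0.617). Of 3 models named cyclin-dependent kinase alone, 0 were higher and 2 lower, and of 9 named cyclin-dependent kinase 2, 1 was higher and 1 lower. Ciclev10002132m, matched to cyclin-dependent kinase B2-2, stood at 96.8 ± 13.5 and 33.8 ± 3.44. Ciclev10001364m, named both as the checkpoint protein MAD1 and as a galactosyltransferase, stood at 26.2 ± 0.717 and 57.1 ± 1.95.

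Of 5 tested seed markers, 3 were higher in kumquat and 2 not called, and 3 were higher adjusted over the list alone (camera adjusted p = 0.113, median 1.41). Ciclev10006308m, matched to the late embryogenesis abundant protein Lea5, stood at 701 ± 85.5 in clementine and 2618 ± 253 in kumquat. The other 2, chosen after their values were seen, were Ciclev10006365m, also Lea5, at 6.18 ± 2.24 and 35.2 ± 3.57, and Ciclev10027019m, a vicilin-like protein, at 30.6 ± 1.49 and 83.2 ± 2.51. The 2 Lea5 models share a protein match, so the 5 models make 4 matches, 2 of them higher when summed. Late embryogenesis abundant proteins also accumulate in other tissues under water stress.

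Auxin models were lower more often than higher, with 33 of 78 lower, 19 higher and 26 not called, and 33 and 21 adjusted over the list alone. The list was not called (camera adjusted p = 0.238, median -0.12). The AUX/IAA repressors of auxin signalling had 16 of 32 models lower and 6 higher (camera adjusted p = 0.269), and 10 of 19 summed matches lower and 5 higher. Ciclev10028271m, an auxin influx carrier, stood at 45.2 ± 2.34 in clementine and 10.9 ± 1.10 in kumquat. Ciclev10019121m, which carries 4 names, among them the auxin-responsive GH3 family and beta-glucosidase, stood at 4.35 ± 0.685 and 68.7 ± 0.659. In the gibberellin list 33 of 89 were higher, 31 lower and 25 not called, with 33 and 32 adjusted over the list alone (camera adjusted p = 0.895, median 0.01). Of 23 models named as the gibberellin receptor GID1, 11 were higher and 7 lower (camera adjusted p = 0.543). Among them, Ciclev10005496m, whose protein match is a carboxylesterase, stood at 13.0 ± 1.80 and 172 ± 15.9, and Ciclev10012177m at 26.8 ± 1.46 and 10.2 ± 0.296.

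The ethylene list had 23 of 66 models higher, 11 lower and 32 not called, and 23 and 11 adjusted over the list alone (camera adjusted p = 0.392, median 0.11). In 26 of the 66 the text pattern met the word inside another, such as methylene. Both examples the naming rule gave are of that kind and are no ethylene genes, Ciclev10016206m (carboxymethylenebutenolidase, 362 ± 18.4 and 749 ± 52.6) and Ciclev10019406m (methylenetetrahydrofolate reductase, 340.5 ± 7.58 and 159 ± 1.48). Of the remaining 40, 15 were higher and 5 lower (camera adjusted p = 0.317). Of 40 MADS-box models, a family of developmental regulators, 14 were higher, 5 lower and 21 not called, the same adjusted over the list alone (camera adjusted p = 0.412, median 0.22). Ciclev10022572m stood at 41.3 ± 5.74 and 91.3 ± 4.11, and Ciclev10021367m at 40.3 ± 2.60 and 15.8 ± 0.930.

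Heat shock models were higher more often than lower, 63 against 35 of 140 with 42 not called, and 65 against 35 adjusted over the list alone. The list was not called (camera adjusted p = 0.113, median 0.28). Of 39 models of the 70 kDa chaperone family 1/8, 25 were higher and 8 lower (camera adjusted p = 0.0624). Of 40 HSP20 models, 11 were higher and 18 lower (adjusted p = 0.604), and of 39 summed matches 14 were higher and 17 lower. Ciclev10027981m, a 70 kDa heat shock protein, stood at 478 ± 6.35 in clementine and 991 ± 9.30 in kumquat. Ciclev10013046m, an HSP20 small heat shock protein, stood at 882.5 ± 59.2 and 208 ± 19.9. Disease resistance (NBS-LRR) models, receptors of plant immunity, had 58 of 190 higher, 73 lower and 59 not called, with 61 and 74 adjusted over the list alone (camera adjusted p = 0.518, median -0.05). Ciclev10020921m stood at 8.68 ± 0.609 and 69.7 ± 9.10, and Ciclev10030216m at 54.6 ± 2.89 and 25.7 ± 3.47.

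The ribosomal protein list had 3 of 19 models higher, 6 lower and 10 not called, the same adjusted over the list alone (camera adjusted p = 0.821). Its pattern caught few of the models so named. In a count added after the data were seen, 479 tested models, these 19 among them, named a ribosomal protein, with 117 higher and 149 lower. The median of this list was 0.08, while its mean of -0.28 and its test had the opposite sign. Ciclev10033065m, ribosomal protein S15a, stood at 33.2 ± 3.96 in clementine and 130.0 ± 15.9 in kumquat. Ciclev10017430m, S27, stood at 97.2 to 116 in the clementine libraries and was listed at 0, 0.38 and 0 in kumquat. The list of transposable elements had 4 tested models, under the minimum of 5, and was not tested. For every model named as a list example, the SE of the log2 change lay between 0.0447 and 0.395, and the limma adjusted p was at most 0.00191.

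**Figure D2:**
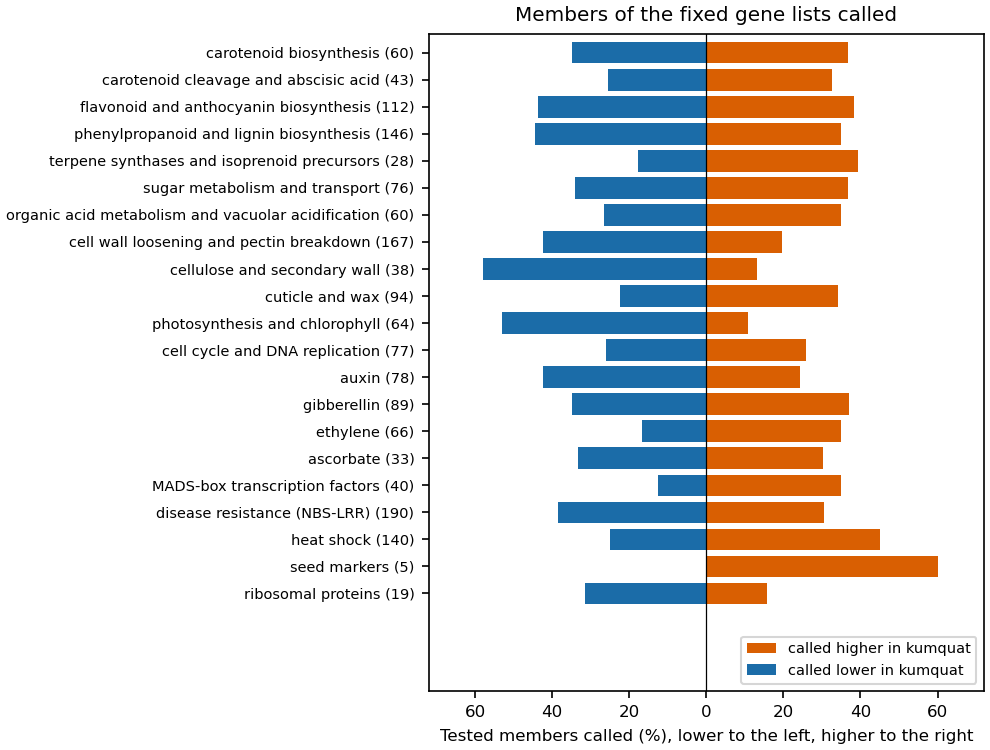
Share of tested members of each of the 21 tested lists that were called higher (orange, to the right) or lower (blue, to the left) in kumquat, in percent, with the number tested in parentheses. The photosynthesis and cellulose lists lean most to the left, with 34 of 64 and 22 of 38 models lower.

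**Figure D3:**
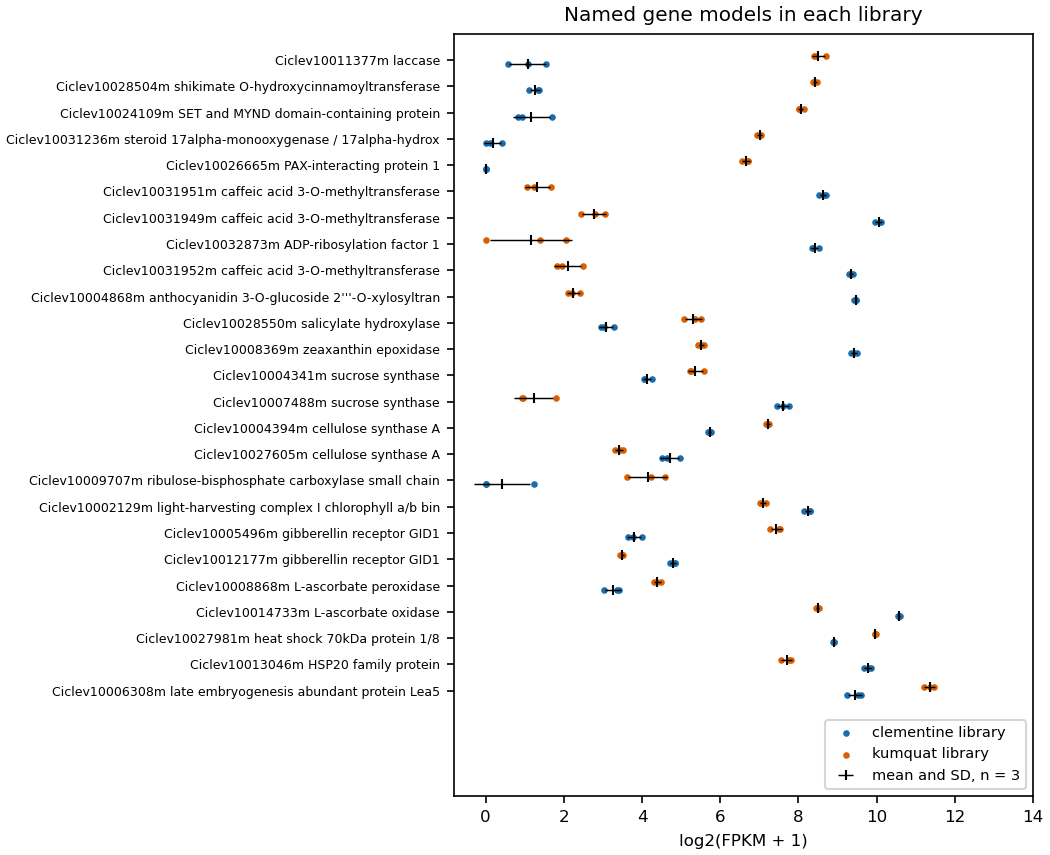
log2(FPKM + 1) in each library for 25 of the 49 named models, with clementine in blue and kumquat in orange. Black crosses show the mean and SD over 3 libraries. Some values of 0 coincide, as for Ciclev10026665m in clementine.

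None of the 3 called lists passed at adjusted p under 0.05 with an estimated correlation. The lists with an unadjusted camera p under 0.05 were then cell wall loosening, heat shock and cellulose, without photosynthesis. The run with an estimated correlation also has far fewer degrees of freedom. The loss of the 3 calls therefore does not show that correlation between genes removes them. Of the 30139 models, 12901 shared their protein match with another model, so fragments could be divided among near-identical models, and 25 of the 49 named models were of this kind.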

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

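Chosen after the results were seen were the sums of models with the same protein match and the narrower ethylene pattern. Across the filters, pseudocount 0.1, median scaling, each library left out and the replicate block, no named model lost its call or its direction. At least 2-fold lower models numbered 1717 with the filter of 5 FPKM, where 15485 models were tested, against 2672. With the correlation between genes estimated, 0 lists were called by camera against 3 with the preset one (at an unadjusted p under 0.05 cell wall loosening, heat shock and cellulose, without photosynthesis). The estimated correlation was 0.0235 for cellulose and 0.0807 for photosynthesis, above the preset 0.01. For cell wall loosening it was -0.00317, below the preset value, yet the unadjusted camera p rose from 0.00394 to 0.00937. A higher correlation therefore does not explain the rise for that list. With an estimated correlation camera takes its degrees of freedom from the few libraries, and with a preset one from the many models. This change alone raises p, whatever the correlation. With no filter on low values the cell wall loosening list had adjusted p = 0.0963, and over its alternatives the adjusted p ran from 0.0158 with the stricter filter to 0.197 with the estimated correlation. Leaving out 1 library at a time gave 5860 to 6216 higher and 5229 to 5842 lower models, 2691 to 2736 and 2614 to 2685 of them at least 2-fold, and 3 lists in each case. Median scaling gave 6162 higher and 6406 lower models, 49.0% higher against 52.5%. Summing models by protein match gave 6074 higher and 5292 lower of 17638 matches. There 3 named models lost their calls, Ciclev10026665m (log2 change 0.13), Ciclev10032873m (-0.17) and Ciclev10009707m (0.07), since the other models of the match moved the opposite way. The replicate numbers are not known to pair libraries. Libraries of the same number had deviations from their group means correlated at 0.119, 0.0424 and 0.0657, and the fit with the replicate block called 6772 higher and 6172 lower models, 2760 and 2689 at least 2-fold, and 3 lists. The alternatives planned for counts were not run because the values are FPKM. Depth is known only relative to another library, so models near 1 FPKM and changes under 2-fold are the least certain.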

Other observations

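The tests of KEGG and GO groups were chosen after the main results were seen, as were the test of kumquat fragments lost against clementine models, the draws of unrelated models and the test of species-only models that share a match. Aquaporins of the plasma membrane, channels for water, were lower in kumquat in all 12 tested models (median log2 change -1.01, camera adjusted p = 0.00488, and adjusted p = 0.869 with an estimated correlation). The most abundant, Ciclev10029003m, stood at 862 ± 67.9 FPKM in clementine and 337 ± 18.8 in kumquat (SD, n = 3 each), and Ciclev10021502m at 665.5 ± 20.3 and 482 ± 16.3. Tubulins and other models of microtubule-based process were lower in 21 of 32 and higher in 3 (median -0.76, adjusted p = 0.000306, and adjusted p = 0.833 with an estimated correlation). Alpha-tubulin Ciclev10025588m stood at 862 ± 41.7 and 279.9 ± 16.1, and beta-tubulin Ciclev10011719m at 468 ± 15.0 and 284 ± 3.13. Glutathione S-transferases, which conjugate glutathione to other compounds, were higher in 29 of 44 models and lower in 5 (median 0.72, adjusted p = 0.0341, and adjusted p = 0.869 with an estimated correlation). The most abundant called member, Ciclev10022212m, was among the 5 lower ones, at 729 ± 36.6 and 515 ± 12.0, and Ciclev10022164m was higher at 226 ± 22.6 and 523 ± 54.0.

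Models named isoflavone-7-O-methyltransferase, which methylate phenolic compounds, were lower in 7 of 10 and higher in 1 (median -2.47, adjusted p = 0.0341, and adjusted p = 0.869 with an estimated correlation). Both examples also carry names of other O-methyltransferases. Ciclev10005279m stood at 173 ± 3.07 in clementine and 1.09 ± 0.377 in kumquat, and Ciclev10015724m at 214.5 ± 18.3 and 7.20 ± 0.748. Models named L-galactose dehydrogenase, an enzyme of ascorbate synthesis, were higher in 10 of 15 and lower in 2 (adjusted p = 0.04995, and adjusted p = 0.869 with an estimated correlation). In the GO term response to stimulus, 43 of 71 models were higher and 19 lower (median 0.53, adjusted p = 0.0385, and adjusted p = 0.998 with an estimated correlation). In all, 8 of 496 KEGG groups and 5 of 301 GO groups passed with the preset correlation. With an estimated correlation 0 of either passed with camera, and 15 and 10 had an unadjusted p under 0.05. That run has few degrees of freedom, so hardly any group could pass it after adjustment over so many groups. It cannot tell whether correlation between genes accounts for these results.

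Of the 4706 protein matches shared by 2 or more models, 198 (4.21%) held at least 1 model called 2-fold higher and 1 called 2-fold lower in kumquat. One hypothesis is that fragments were divided differently among models of the same locus, because kumquat sequence differs from the clementine models. In 172 of the 198 matches (86.87%, exact 95% interval 81.35 to 91.24) the sums differed less than 2-fold, but opposite calls favour sums that cancel. When each lower model was replaced by a lower model of another match with a similar level, in 1000 draws, the median share was 83.84% and the upper 2.5 percent point 86.36%, so the observed share lay only slightly above what unrelated models gave. Such a division may account for some matches, as may differences in transcript form between the species. The sums of the other 26 matches differed at least 2-fold. FPKM are scaled to model length, so a division among models of unequal length can change a sum, and these sums do not exclude it.

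Some models were seen in 1 species only, taken as at least 10 FPKM in all 3 libraries of one species and at most 0.5 in all 3 of the other. There were 81 such models for clementine and 47 for kumquat, of which 34 and 18 were listed at 0 throughout in the other species. Loss of kumquat fragments against clementine models cannot give the 47 kumquat-only models. It could add to the clementine-only ones, which were 63.28% of the total (exact 95% interval 54.31 to 71.62, exact binomial p = 0.00337, two-sided), but a true difference in expression or gene content gives the same excess and the explanations cannot be told apart. The binomial test takes models as independent, though some share a protein match. With models summed by match, 51 matches were clementine-only and 35 kumquat-only, a smaller excess. A different division of fragments among models stays open too. Sums differed less than 2-fold for 30.86% of the clementine-only and 19.15% of the kumquat-only models, but 43 and 33 of them share their match with no other model and are their own sum. Among the 38 and 14 that share one, the shares were 65.79% (48.65 to 80.37) and 64.29% (35.14 to 87.24), intervals that hold 50%.

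Models annotated as LHY, a clock transcription factor that peaks in the morning, were lower in kumquat in 12 of 16 and higher in 1 (median -1.22, camera adjusted p = 0.0341, and adjusted p = 0.869 with an estimated correlation). They belong to 7 protein matches, 4 lower and 1 higher when summed, and the camera test on these sums gave an unadjusted p = 0.0657. A hypothesis is that fruit of the 2 species was picked at different hours, which predicts that later-peaking clock genes move the other way. Of 27 such models 11 were higher and 6 lower (median 0.4291, and 10 higher and 3 lower of 19 summed matches), among them GIGANTEA (Ciclev10004044m, 58.9 ± 4.83 and 252 ± 15.8) as higher and a pseudo-response regulator 1 (Ciclev10019534m, 31.7 to 36.7 and 22.1 to 23.4) as lower. The direction goes with the hypothesis, but as a set these models did not pass camera (unadjusted p = 0.101, or 0.176 with an estimated correlation), no label gives the hour of picking, and fruit age and species remain open.

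Among the 10 splits of the 6 libraries into 3 and 3, the real one called 12582 models and 5413 at least 2-fold, and the others at most 0 with limma (130 to 308 at an unadjusted p under 0.05, against 13589). For lists, the real split called 3 and the highest other 2. In each case 1 split, the real one, reached the real value, and 10 splits are too few for a share under 0.05. Every other split also puts both species in each group, so the species difference widens its spread within groups. Few model calls there were thus set by the design, and the comparison cannot weigh chance.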
